A study of Rattus norvegicus with 6 samples.

How the data were processed

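Lung RNA of 6 Lewis rats, 3 exposed to silica by inhalation and 3 kept in filtered air, was measured on 1-colour short-oligonucleotide arrays, 1 array per animal. Per the labels' protocols, lung tissue was homogenised in a phenol-based reagent, RNA was extracted, and biotin-labelled cRNA was made by in vitro transcription. The deposited values are linear signal intensities, 1 per probe set and array, with 1 decimal and none below 0.1. The software that summarised the probes, its scaling and any filter are not given in the sources used here. From the values, each array had a mean between 500.14 and 500.15 after trimming 2% of probe sets at each end, so the deposited intensity values had been scaled by 1 factor per array. Such scaling keeps differences in the shape of the distribution between arrays.

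The table held 31099 probe sets, of which 57 were control probe sets of the array and were not among the probe sets compared. Gene names came from the platform annotation given for these probes, with symbols updated through the gene identifier to a RefSeq table of the rat assembly GRCr8, whose coordinates were not used. Of the probe sets, 20826 had 1 gene, of which 20758 matched by identifier, 436 had several genes and gave no name, and 9780 were not listed and are unnamed here. A gene was represented by its brightest probe set over all arrays, which gave 14217 genes.

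Values were analysed as log2(signal + 16), with a pseudocount of 16. Array medians on this scale lay within 0.2 of each other, so no further normalization was applied. Samples were grouped by their titles. Silica was compared with control by limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the single term, 4 residual and 2.18 prior degrees of freedom, and Benjamini-Hochberg adjustment over 31042 probe sets at a threshold of 0.05. The 26 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the lists with at least 5 measured genes. The first 6 lists cover the study's declared subject. Camera with an estimated correlation and the self-contained test fry were run beside it. An exact permutation test of 3 against 3 cannot give a p under 0.1.

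Genes to name were chosen by a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls, by the brightest probe set of each gene, past the threshold with all arrays of the groups apart. It left out genes without an established symbol and genes with a mean log2 value under 5.59 in both groups. It added up to 4 members with the smallest p in each of the 6 lists of the declared subject and 2 in each other list. It also took 17 genes of the study's subject whatever their values: Tgfb1, Ccn2, Col1a1, Col3a1, Fn1, Spp1, Mmp12, Timp1, Sod2, Hmox1, Nqo1, Gclc, Tnf, Il1b, Il6, Nos2 and Ccl2.

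Alternatives fixed before the data were examined were quantile normalization, centring each array on its median, leaving out the dimmer 50% of probe sets, eBayes with an intensity trend and robust spread, the replicate number as a block, pseudocounts of 1 and 64, array weights, each array left out in turn, thresholds of adjusted p 0.01 and of 2-fold, no moderation of the spread, and the mean of all probe sets of a gene. A covariate for RNA quality (mean log2 3-prime to 5-prime signal ratio of beta-actin and GAPDH) and leaving out control replicate 3 together with silica replicate 1 were added after seeing the data.

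The fit was tested on simulated arrays with the means and spread of the 31042 probe sets, in which 200 probe sets were changed. Of 50 probe sets each, 0% were recovered at a log2 change of 0.5, 34% at 1, 88% at 2 and 100% at 4. None had the wrong sign, and 3 unchanged probe sets were called. The unadjusted p needed to pass depends on how many probe sets change, and the spread used was the moderated one. These rates therefore need not hold for the real comparison. With 1 of the 26 lists shifted by 1 on the log2 scale over 14217 genes, camera called that list and 0 others. Genes were simulated independently, so this does not test calls on lists with correlated genes. In the real lists the estimated correlation reached 0.56 (cardiac muscle).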

Results

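Gene expression was measured in lung tissue of Lewis rats, an inbred strain, with 1 array per animal. The silica group held 3 animals that breathed an aerosol of silica dust at 6.2 mg/m3 for 6 hours a day, 5 days a week, over 6 weeks. The control group held 3 animals that breathed filtered air. The time between the last exposure and tissue collection is not given in the sources used here. Each array gave a signal for 31042 probe sets apart from the control probe sets, among them probe sets for 14217 named genes. A gene's values, and the counts of genes in each list, are those of its brightest probe set, with p adjusted over all probe sets unless stated. Array medians on the log2 scale lay between 7.38 and 7.42. The number of arrays limits the precision of every value. Signals are given as mean ± SD (n = 3 animals per group), and log2 fold changes (silica minus control) as the estimate ± SE on the log2(signal + 16) scale, which understates the change of dim genes.

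The comparison asked which genes differed between silica-exposed and control lungs, with fibrogenic, redox-related and proinflammatory genes as its declared subject. Lactoperoxidase (Lpo), a secreted peroxidase, had the largest rise, from 18.3 ± 13.1 to 1627 ± 478 (log2 fold change 5.61 ± 0.31, adjusted p = 0.00970). The acute-phase genes Saa3 and Orm1 rose from 95.7 ± 20.1 to 1452 ± 504 and from 25.2 ± 4.21 to 506 ± 186. Mmp12, the macrophage elastase, rose from 121 ± 54.0 to 1306 ± 265 (log2 fold change 3.33 ± 0.32, adjusted p = 0.0255). The chemokine genes Ccl2, Ccl7, Cxcl9 and Cxcl11 were also among the 12 largest rises, with log2 fold changes of 2.99, 2.80, 3.10 and 3.10. The others were the secretin receptor gene Sctr (2.40 ± 0.300 to 128 ± 22.3), the anion exchanger gene Slc26a4 (142 ± 23.0 to 1076 ± 107), the ubiquitin-like modifier gene Ubd (178 ± 42.9 to 1278 ± 712) and the metallothionein gene Mt3 (12.5 ± 5.93 to 139 ± 47.0). Lpo, Orm1, Sctr and Mt3 were dim in control. Their log2 fold changes ran from 4.34, 2.63, 1.53 and 1.39 with pseudocount 64 to 6.56, 4.22, 5.24 and 3.44 with pseudocount 1, so the order of the rises depends on the pseudocount, with Lpo first of the 12 in both. With pseudocount 1 Mt3, Mmp12, Cxcl9, Cxcl11, Ccl7 and Ubd did not pass.

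The largest falls were smaller than the largest rises, by the brightest probe set of each gene. Sema3a, an axon guidance gene, fell from 66.2 ± 11.8 to 11.2 ± 8.79 (log2 fold change -1.63 ± 0.24, adjusted p = 0.0468), and Cpa1 and Mslnl fell from 39.8 ± 14.5 to 4.77 ± 1.63 and from 40.0 ± 10.2 to 8.30 ± 2.36. These 3 genes were dim in silica, so their log2 fold changes, and the order of the largest falls, depend on the pseudocount. With pseudocount 1 Sema3a, Cpa1 and Mslnl had -2.69, -2.81 and -2.14, none past the threshold, and with pseudocount 64 -0.79, -0.58 and -0.52, behind Serpinb10, whose log2 fold change was -0.99 or stronger in every alternative. Serpinb10, a serine protease inhibitor gene, was the brightest of the 12 and fell from 2529 ± 165 to 1196 ± 218 (log2 fold change -1.08 ± 0.15, adjusted p = 0.0446). The proprotein convertase gene Pcsk6, Pitpnm3, the adhesion receptor gene Adgrv1 and the growth factor gene Bmp3 fell, with log2 fold changes of -0.87, -0.81, -0.75 and -0.71. Elavl2, Bmal1, Arhgap20 and Bmyc completed the list with -0.93, -0.89, -0.76 and -0.68. Elavl2 had 2 further probe sets, neither past the threshold, with log2 fold changes of -1.10 and 0.44, so its probe sets differed in sign, and a further Arhgap20 probe set had -0.21. A further 12 genes fell in a dimmer probe set while their brightest one did not pass. Named after their values were seen, these include Wnk1 (-1.69, brightest probe set 0.06), Ppp4r3a (-1.56, brightest 0.03), Foxf1 (-1.42, brightest -0.35), Sox2 (-1.17, brightest -0.40) and Epha4 (-1.08, brightest -0.65).

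In all, 290 probe sets rose and 45 fell at a limma adjusted p under 0.05, out of 31042. By brightest probe set 221 genes rose and 17 fell, and by any probe set 236 rose and 29 fell. Of the probe sets, 164 higher and 19 lower changed at least 2-fold. In each of the 335 probe sets the 3 silica arrays lay on 1 side of the 3 control arrays. Passing the threshold makes this nearly certain, so it adds no evidence. Over all probe sets 25.6% separated in this way, where chance gives 10%. The probe sets that fell had a median control signal of 75.2, against 232 for those that rose. The count rested on having all 6 arrays: 0 probe sets passed without control replicate 1, control replicate 3 or silica replicate 3. There was 1 without control replicate 2, 12 without silica replicate 1 and 3 without silica replicate 2, each higher in silica, so the calls on single genes hold for the 6 arrays together. Under other settings between 0 (a covariate for RNA quality, added after seeing the data) and 1862 probe sets (an intensity trend with robust spread) passed. The balance also moved, with 1141 higher and 721 lower under that trend, and 1044 and 631 with the dimmer 50% left out. At an unadjusted p under 0.05, limma gave 5369 probe sets with all arrays (2903 higher and 2466 lower) and between 4024 and 5427 with 1 array left out.

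**Figure D1:**
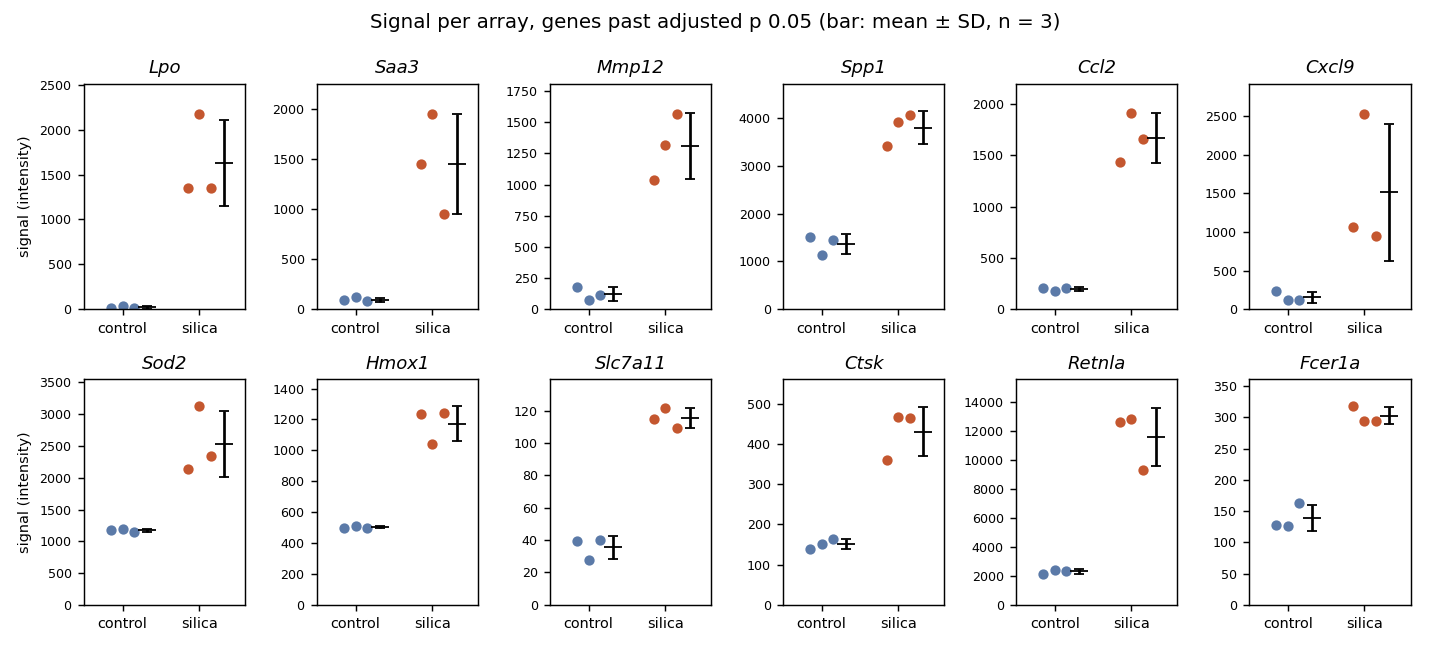
Signal (linear intensity) of 12 genes past an adjusted p of 0.05 in each of the 3 control arrays (blue) and 3 silica arrays (orange), with the mean ± SD beside the points. In every panel the 3 silica arrays lie above the 3 control arrays, and Lpo goes from 18.3 to 1627.

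Chemokine genes rose in 10 of 28 cases over all probe sets, none fell, and 16 were higher when adjusted over the list alone. Ccl2, which attracts monocytes, rose from 195 ± 20.02 to 1669.6 ± 241 (log2 fold change 2.99 ± 0.14, adjusted p = 0.00947), and Ccl7, a related monocyte attractant, from 50.5 ± 19.3 to 438 ± 78.1. Ccl9 rose from 1689.6 ± 109 to 5577 ± 502 and Ccl3 from 278 ± 19.8 to 794 ± 41.3. The list had a median log2 fold change of 0.97 and shifted upward against other genes (camera, adjusted p = 1.25e-09). It did not pass with an estimated correlation (adjusted p = 0.0766 with an estimated correlation). Cxcl9 and Cxcl11, chemokine genes induced by interferon gamma, had wide SDs among the silica animals, and rose from 154 ± 71.9 to 1513 ± 884 and from 59.6 ± 20.3 to 691 ± 421.

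Of 31 proinflammatory cytokine and NF-kB genes, 1 passed over all probe sets. It was Pycard, an inflammasome adaptor gene, which rose from 1047 ± 19.6 to 1748 ± 162 (log2 fold change 0.73 ± 0.11, adjusted p = 0.0458). Adjusted over the list alone, 4 members were higher and 2 lower. Tnf had 60.3 ± 24.7 in control and 203 ± 55.0 in silica (log2 fold change 1.54 ± 0.28, adjusted p = 0.0767), and 0.72 in a further probe set. Il1b had a log2 fold change of 0.79 ± 0.25 (adjusted p = 0.196), Il6 of 0.92 ± 0.27 (adjusted p = 0.173) and Nos2, the inducible nitric oxide synthase gene, of 0.78 ± 0.58 (adjusted p = 0.540). Ltb had 0.73 and Il12a -0.69, neither past the threshold. Il12a was dim in both groups (25.1 ± 1.07 in control and 9.67 ± 3.11 in silica), and Il6 in control (19.1 ± 9.99). Over the alternatives Il12a ranged from -1.33 to -0.28 and Il6 from 0.45 to 1.405. The list as a whole had a median of 0.34 and shifted upward (camera, adjusted p = 0.00775), but not with an estimated correlation (adjusted p = 0.298 with an estimated correlation).

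Of 35 measured genes of antioxidant and Nrf2 defence, 5 rose and none fell over all probe sets. Adjusted over the list alone, 7 were higher and 3 lower. Heme oxygenase 1 (Hmox1) rose from 503 ± 6.00 to 1173 ± 114 (log2 fold change 1.19 ± 0.11, adjusted p = 0.0246). Slc7a11, the cystine transporter of glutathione synthesis, rose from 35.6 ± 7.05 to 115 ± 6.23, and Srxn1, sulfiredoxin, from 172 ± 27.7 to 479 ± 35.3. Of 2 further Srxn1 probe sets, neither past the threshold, 1 had the opposite sign. Mitochondrial superoxide dismutase (Sod2) rose from 1172 ± 20.9 to 2535 ± 522 (log2 fold change 1.08 ± 0.16, adjusted p = 0.0458). Hp, the hemoglobin-binding acute-phase gene, rose from 836 ± 14.1 to 2503 ± 617. Nqo1 and Gclc, both standard Nrf2 targets, had log2 fold changes of 0.09 ± 0.11 (adjusted p = 0.722) and 0.11 ± 0.14 (adjusted p = 0.726), and a further Gclc probe set had -0.26. The list did not shift as a set: its median was -0.05, its mean 0.18 and its camera adjusted p 0.802. The median turned positive without control replicate 3 (0.01), silica replicate 1 (0.05) or silica replicate 3 (0.01). With an estimated correlation the adjusted p was 0.877.

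Among 18 oxidant-producing enzyme genes 3 rose. Besides Lpo these were the NADPH oxidase subunit genes Cyba (1600.2 ± 177 to 3308 ± 319, adjusted p = 0.0394) and Rac2 (3190.3 ± 208 to 5137 ± 147, adjusted p = 0.0458). Cybb, the catalytic subunit of the phagocyte oxidase, had a log2 fold change of 0.56 ± 0.13 (adjusted p = 0.121), and a further Cybb probe set was close to 0 (0.03). Adjusted over the list alone, 6 were higher and 2 lower. The list median was 0.26, and the set did not pass (camera, adjusted p = 0.057; adjusted p = 0.298 with an estimated correlation). Without silica replicate 1 or silica replicate 2 the camera adjusted p was 0.023 and 0.0483. The list also passed with quantile normalization (0.0454), median centring (0.0483), the replicate block (0.0419), array weights (0.0413), pseudocount 64 (0.0364), the mean of all probe sets (0.0459) and the dimmer 50% left out (0.000133), so whether it passes depends on the setting. Its median was 0.59 with the dimmer 50% left out, 0.43 without silica replicate 1 and 0.16 without silica replicate 3.

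Of 39 measured genes of fibrosis and extracellular matrix, 1 passed over all probe sets. This was osteopontin (Spp1), a secreted matrix glycoprotein, which rose from 1366 ± 211 to 3802 ± 341 (log2 fold change 1.47 ± 0.15, adjusted p = 0.0298). Tgfb1, the profibrotic growth factor gene, had 506 ± 56.5 in control and 762 ± 44.7 in silica (log2 fold change 0.58 ± 0.12, adjusted p = 0.0938) and counted as higher when adjusted over the list alone, as 1 of 2 genes. Col1a1 had a log2 fold change of 0.43 ± 0.15 (adjusted p = 0.225), Col3a1 of 0.09 ± 0.17 (adjusted p = 0.829), Fn1 of 0.07 ± 0.11 (adjusted p = 0.799) and Ccn2 of 0.00 ± 0.13 (adjusted p = 0.997). Igf1 had 0.45 and Sparc -0.42, neither past the threshold. Further probe sets of Col1a1 and Sparc had 0.20 and -0.23, and those of Igf1 0.21 and 0.24. The list median was -0.11 and its mean -0.0022, with no shift as a set (camera, adjusted p = 0.0950; adjusted p = 0.370 with an estimated correlation). Without silica replicate 2 the camera adjusted p was 0.0285, and with the dimmer 50% left out 0.0479, both in the downward direction. Without control replicate 3 the median was -0.06 (camera, adjusted p = 0.517).

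Of 31 measured matrix proteases and inhibitors, 5 rose, and 9 were higher when adjusted over the list alone. Mmp12 was among them. Mmp9, a gelatinase, rose from 56.0 ± 0.493 to 236 ± 34.3 (log2 fold change 1.80 ± 0.13, adjusted p = 0.0127). The lysosomal cathepsin genes Ctsk and Ctsz rose from 151 ± 12.5 to 431 ± 61.3 and from 1733 ± 109 to 3717 ± 474, and Ctss, named after its values were seen, from 4036 ± 91.9 to 7534 ± 864. Timp1, a metalloproteinase inhibitor gene, had a log2 fold change of 0.85 ± 0.14 (adjusted p = 0.0604). The list shifted upward (median 0.14, camera adjusted p = 0.0259), but not with an estimated correlation (adjusted p = 0.120 with an estimated correlation) and not without silica replicate 3, where the camera adjusted p was 0.0578.

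**Figure D2:**
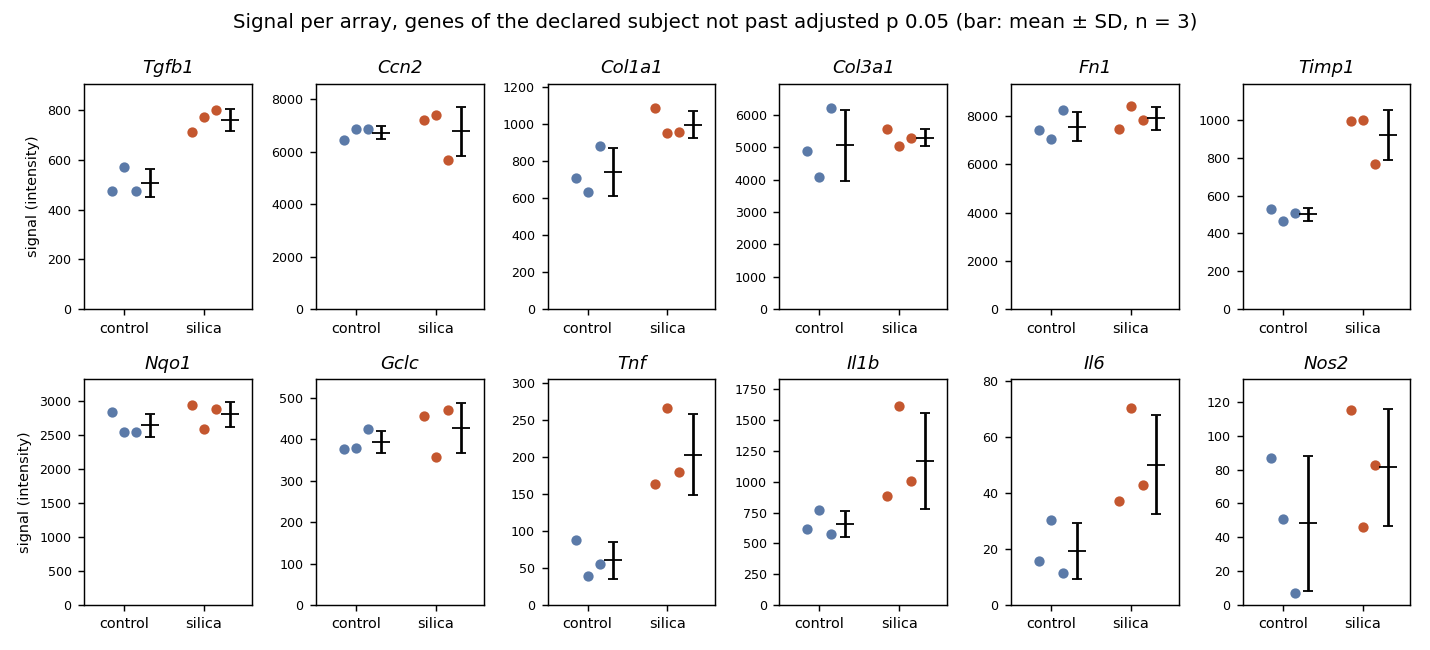
Signal (linear intensity) of 12 genes from the study's declared subject that did not pass an adjusted p of 0.05, in 3 control arrays (blue) and 3 silica arrays (orange), with the mean ± SD beside the points. Col3a1, Fn1, Ccn2, Nqo1, Gclc and Nos2 overlap between the groups. Tnf, Timp1 and Tgfb1 separate but miss the threshold (adjusted p 0.0767, 0.0604 and 0.0938), as do Col1a1, Il1b and Il6 (0.225, 0.196 and 0.173).

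Macrophage genes rose in 8 of 27 cases over all probe sets, and 15 were higher when adjusted over the list alone. Retnla, a marker of alternatively activated macrophages in rodents, rose from 2299.6 ± 146 to 11566 ± 1981 (log2 fold change 2.31 ± 0.15, adjusted p = 0.0127), and the acidic chitinase gene Chia from 4842 ± 299.8 to 17468 ± 2528. Retnla and Chia are also made by lung epithelium. With a median of 0.62 the macrophage list shifted upward (camera, adjusted p = 4.17e-09; adjusted p = 0.0659 with an estimated correlation). Among 8 neutrophil genes 2 rose, Lcn2 from 5083 ± 309 to 19150.0 ± 3089 and the decoy receptor gene Il1r2 from 58.5 ± 16.8 to 204 ± 49.4. Lcn2 is also an acute-phase gene of epithelium. The neutrophil list had a median of 0.80 (camera, adjusted p = 0.00226; adjusted p = 0.298 with an estimated correlation), which was 0.53 without silica replicate 2.

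Genes of mast cells, basophils and eosinophils followed with 3 of 17 higher. The mast cell protease gene Mcpt1 rose from 91.9 ± 4.40 to 384 ± 106, the IgE receptor gene Fcer1a from 139 ± 20.5 to 302 ± 13.5, and Mcpt10, named after its values were seen, from 220.4 ± 27.9 to 643 ± 163. The list of these cells had a median of 0.44 (camera, adjusted p = 0.00123; adjusted p = 0.120 with an estimated correlation). T and NK cell genes rose in 8 of 21 cases and in 16 when adjusted over the list alone. The T cell receptor kinase gene Zap70 rose from 227 ± 14.6 to 494 ± 29.0 (log2 fold change 1.07 ± 0.10, adjusted p = 0.0255) and the CD3 chain gene Cd3d from 195 ± 28.2 to 490.3 ± 63.4, while a further Zap70 probe set had 0.47 and did not pass. The T and NK list median was 0.93 (camera, adjusted p = 7.59e-10; adjusted p = 0.0766 with an estimated correlation). No B and plasma cell gene of 11 passed over all probe sets, and 4 were higher when adjusted over the list alone. Jchain had a log2 fold change of 0.80 ± 0.21 and Cd22 of 0.41 ± 0.11. The B cell list shifted upward by camera (median 0.34, adjusted p = 0.0163), but not with an estimated correlation (adjusted p = 0.298 with an estimated correlation) and not without silica replicate 3 (camera, adjusted p = 0.0947).

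Antigen presentation genes rose in 3 of 18 cases over all probe sets and in 15 when adjusted over the list alone. The class II chain gene RT1-Db1 rose from 2818 ± 167 to 5293 ± 214 and the class II transactivator gene Ciita from 241 ± 21.8 to 499 ± 65.1, and RT1-Bb, named after its values were seen, from 6196 ± 214 to 12176 ± 1739. Antigen presentation genes had a median of 0.71 (camera, adjusted p = 1.63e-09; adjusted p = 0.192 with an estimated correlation). Of 14 complement genes 7 rose, among them Cfi from 569 ± 39.1 to 1520.4 ± 59.2 and C1qa from 669 ± 81.6 to 1876 ± 69.5. The complement list had a median of 0.66 (camera, adjusted p = 1.14e-06; adjusted p = 0.120 with an estimated correlation). Among 20 interferon-response genes 1 passed, Stat2, which rose from 784 ± 90.4 to 1685 ± 173. Mx1 had a log2 fold change of 0.54 ± 0.09 (adjusted p = 0.0691). The interferon list had a median of 0.29 (camera, adjusted p = 0.000999; adjusted p = 0.298 with an estimated correlation). Its mean above the controls was 0.60 in silica replicate 2, against 0.31 and 0.24 in the other silica arrays.

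Cell cycle genes rose in 8 of 23 cases over all probe sets and in 19 when adjusted over the list alone, with 1 lower. The proliferation marker gene Mki67 rose from 161 ± 20.8 to 541 ± 61.8 (log2 fold change 1.65 ± 0.14, adjusted p = 0.0181) and the mitotic gene Cdc20 from 102 ± 2.10 to 277 ± 37.8, while 4 further Cdc20 probe sets, none past the threshold, ranged from 0.07 to 1.29. For the cell cycle list the median was 0.96 (camera, adjusted p = 6.06e-12; adjusted p = 0.0766 with an estimated correlation). Of 20 lysosome and phagosome genes 1 rose, the acid phosphatase gene Acp5, from 1019 ± 37.2 to 1769 ± 35.7, and Ctsa had a log2 fold change of 0.63 ± 0.10 (adjusted p = 0.0555). The lysosome list shifted upward (median 0.23, camera adjusted p = 1.58e-06; adjusted p = 0.120 with an estimated correlation). None of 20 genes of cholesterol and lipid synthesis passed by its brightest probe set, and 2 were higher when adjusted over the list alone, Cyp51 (0.56) and the fatty acid synthase gene Fasn (0.57). A dimmer Fasn probe set rose (log2 fold change 0.75, adjusted p = 0.0422). That list had a median of 0.20 (camera, adjusted p = 0.000528; adjusted p = 0.0766 with an estimated correlation).

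Endothelial and alveolar type 1 genes lay lower in silica as sets, although no member passed over all probe sets. Of 16 endothelial genes 15 had a negative log2 fold change, and 6 were lower when adjusted over the list alone. Car4, of capillary endothelium, had 1386 ± 73.1 in control and 949 ± 95.4 in silica (log2 fold change -0.54 ± 0.12, adjusted p = 0.1002), and Flt1, a VEGF receptor gene, had -0.73 ± 0.19 (adjusted p = 0.147). A further Car4 probe set had -0.10, and of 2 further Flt1 probe sets 1 was close to 0 (0.01). The endothelial list had a median of -0.28 (camera, adjusted p = 6.16e-06; adjusted p = 0.0766 with an estimated correlation). Of 14 type 1 cell genes 13 had a negative log2 fold change, with -0.37 for Emp2 (-1.14 in a further probe set) and -0.34 for the water channel gene Aqp5. The type 1 list had a median of -0.25 (camera, adjusted p = 8.66e-06; adjusted p = 0.120 with an estimated correlation). Type 2 cell genes did not shift (median 0.05, camera adjusted p = 0.576), with Muc1 at 0.46 and Cebpa at 0.41, where further Cebpa probe sets ranged from -0.12 to 0.52. A sign of RNA quality moved with the groups: the GAPDH signal ratio of the 3-prime to the 5-prime control probe set was 1.23 ± 0.0782 in control and 1.501 ± 0.190 in silica, each silica array above each control array.

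Airway epithelium genes did not shift as a set (median -0.13, camera adjusted p = 0.152), while the claudin gene Cldn10 rose from 331 ± 14.8 to 539.6 ± 4.81 and the basal cell keratin gene Krt5 had -0.74 ± 0.20 (adjusted p = 0.163). Smooth muscle genes had a median of -0.11 (camera, adjusted p = 0.0880), with Cald1 at -0.31 and Mylk at -0.23. Genes of heart muscle, which in rodents also lines pulmonary veins, had a median of -0.20 (camera, adjusted p = 0.564), with Nppa at -0.27 and Ryr2 at 0.18, although a further Ryr2 probe set had -0.96. Without control replicate 2 these 3 lists shifted downward (camera, adjusted p = 0.0074, 0.0188 and 0.0053). Without silica replicate 2 the smooth muscle list had 0.0377, and without silica replicate 1 the cardiac list had 0.047. Without control replicate 3 the smooth muscle median was -0.03 (camera, adjusted p = 0.634). The cardiac median turned positive without control replicate 1 (0.38), control replicate 3 (0.02), silica replicate 2 (0.27) or silica replicate 3 (0.10), so its sign depends on single arrays. The airway median was -0.08 without silica replicate 1. Blood and fat genes lay lower (median -0.48, camera adjusted p = 0.0104; adjusted p = 0.120 with an estimated correlation) with none of 9 past over all probe sets. Their median was -0.21 without control replicate 3 and -0.74 without control replicate 2. Adipoq, an adipocyte gene, had a signal of 211, 31.7 and 753 in the 3 control arrays, and Alas2, an erythroid gene, had a log2 fold change of -0.48 ± 0.26.

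Genes of the immediate early and heat shock list did not shift (median -0.00, camera adjusted p = 0.977; median 0.25 without control replicate 1 and -0.05 without control replicate 3), with Atf3 at 0.65 and Egr2 at 0.50 (0.14 in a further probe set), neither past the threshold. In the circadian clock list 1 gene rose and 1 fell. Bhlhe41, a clock-controlled repressor gene, rose from 1064 ± 74.7 to 2128 ± 123 (log2 fold change 0.99 ± 0.11, adjusted p = 0.0307), and Bmal1, the clock's core activator gene, fell from 381 ± 27.9 to 199 ± 20.7 (log2 fold change -0.89 ± 0.12, adjusted p = 0.0411). Adjusted over the list alone, 6 were higher and 2 lower. The list median was 0.36 (camera, adjusted p = 0.0448; adjusted p = 0.397 with an estimated correlation). The camera call was lost without control replicate 3 (0.0601), silica replicate 1 (0.0933) or silica replicate 3 (0.114).

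**Figure D3:**
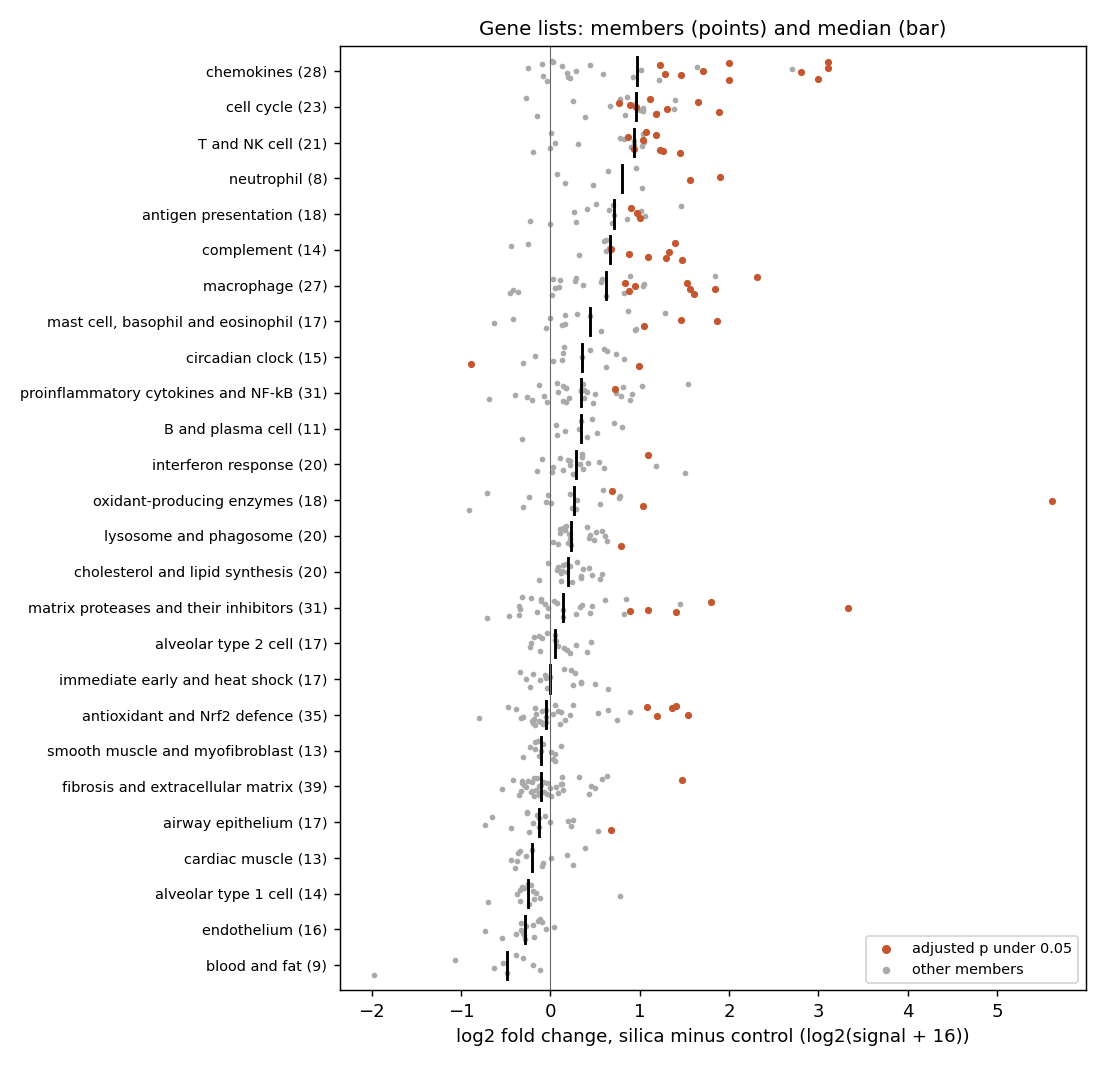
Log2 fold change, silica minus control, on the log2(signal + 16) scale, of each member (points) of the 26 gene lists, with the number of measured genes in brackets, the list median (black bar) and members past an adjusted p of 0.05 in orange. Chemokine, cell cycle and T and NK cell lists have the highest medians (0.97, 0.96 and 0.93), and the blood and fat, endothelium and alveolar type 1 lists the lowest (-0.48, -0.28 and -0.25).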

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

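The tests of RNA degradation and of dilution in this part were chosen after the result was seen, and that of signal-dependent scaling before. The control probe sets, which the main comparison did not use, held a signal above the level of the control animals. The GAPDH ratio of 3-prime to 5-prime signal averaged 1.501 ± 0.190 in silica and 1.23 ± 0.0782 in control (SD, n = 3). The silica arrays had 1.68, 1.52 and 1.30, all above the highest control at 1.27 (exact permutation p = 0.1, two-sided, the smallest this design allows). The beta-actin ratio was 5.03 ± 1.16 in silica and 3.999 ± 0.437 in control, with overlap (exact permutation p = 0.3).

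Endothelial and alveolar type 1 genes lay lower in silica, with a mean log2 difference of -0.24 ± 0.02 (SE over arrays) over 29 genes, leaving out the gene shared with the type 2 list. RNA degradation as a whole cause is argued against by the fit with the 3-prime to 5-prime ratio as covariate, in which the difference was -0.27 ± 0.03. Signal-dependent scaling is argued against by 10000 random lists matched on signal level, whose mean was 0.00585 and whose lowest value was -0.17. Dilution by added leukocyte RNA alone would lower all resident cell types alike. Type 2 cell genes lay 0.31 ± 0.07 (SE over genes) above the endothelial and type 1 genes. This SE takes genes as independent, while the type 2 list had an estimated correlation of 0.41. Smooth muscle genes had a mean of -0.08 ± 0.04 (SE over genes), smaller in size than -0.24. Airway genes had -0.08 ± 0.09, too imprecise to be told from -0.24. Both lists shifted downward by camera without control replicate 2, so they do not decide on dilution. A rise within type 2 cells, or expression of type 2 list genes by leukocytes, stays open. The effect of silica on these cell types, the difference the design names, may account for the pattern as a hypothesis found and tested on the same arrays, and unequal changes in cell numbers stay open.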

How the results depend on the processing

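The RNA quality covariate and the fit without 2 arrays were chosen after seeing the data. Probe sets higher and lower numbered 290 and 45. Filters and spread models moved these counts: 1044 and 631 with the dimmer 50% left out (fewer probe sets tested), 1141 and 721 with an intensity trend and robust spread, 707 and 212 with pseudocount 64, and 39 and 4 with pseudocount 1. Stricter thresholds left 164 and 19 at 2-fold and 6 and 0 at adjusted p 0.01, and without moderation of the spread 30 and 10 passed. With quantile normalization, median centring or array weights both counts stayed within 1.5 times. Leaving out 1 array gave 0 to 12 higher and 0 lower in each fit. With the 3-prime to 5-prime ratio as covariate 0 and 0 passed in limma, with 3184 at an unadjusted p under 0.05, and without control 3 and silica 1 also 0 and 0, with 3590. These fits have fewer degrees of freedom. In each moderated fit the 335 probe sets kept their sign and an unadjusted p under 0.05 (234 of 234 where the dimmer 50% was left out), which is not independent evidence, since they were chosen on the same arrays.

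The replicate block gave 1 probe set higher and 0 lower, with 5190 at an unadjusted p under 0.05. The labels do not say whether a shared number marks a pair. Deviations of same-numbered samples correlated at 0.0924, 0.0350 and 0.0875, none above 0.1, and those of other pairs between -0.0785 and -0.00219. Each of the 6 samples correlated best with its own number, a hint from the data and not the design. The 6 matches are not independent, since deviations were taken from the mean of each group. A weak pairing stays open.

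For gene lists the values are camera adjusted p. Oxidant-producing enzymes (0.057) passed with quantile normalization (0.0454), median centring (0.0483), the dimmer 50% left out (0.000133), the replicate block (0.0419), pseudocount 64 (0.0364), array weights (0.0413), the mean of all probe sets (0.0459), the covariate (0.0133) and without 2 arrays (0.0279), and ranged from 0.023 to 0.116 with 1 array left out. Fibrosis genes passed downward with the dimmer 50% left out (0.0479) and ranged from 0.0285 to 0.517 with 1 array left out. Matrix proteases did not pass with the dimmer 50% left out (0.110) and ranged from 0.0125 to 0.0578. Camera with an estimated correlation ended the call of every list called at the preset one (0.0659 or more). Among these were matrix proteases (0.120), proinflammatory genes (0.298) and chemokines (0.0766). The estimated correlations of the matrix protease, macrophage, endothelium and cholesterol lists were -0.0017, 0.0019, -0.00071 and -0.018. These lie below the preset 0.01, so correlation between genes does not account for the lost calls of these lists. In the clock list the call ended with the mean of all probe sets of a gene (0.350), pseudocount 1 (0.0542) and without 2 arrays (0.130). The test fry asks another question. Its directional form asks whether the genes of a list changed in a common direction, not whether they moved against other genes. Its adjusted p was 0.00345 for oxidant-producing enzymes, 0.0460 for antioxidant genes, 0.0608 for the clock list and 0.0530 for B and plasma cells. The form of fry for change in either direction gave an unadjusted p of 3.6e-07 for fibrosis genes and 3.1e-06 for antioxidant genes. For these lists the lack of a shift as a set therefore does not mean that no member changed. Airway genes had 3.0e-05 in that form, so a low value is not particular to these lists. The cause of the moves between settings was not tested. The 56 named genes past the threshold kept their direction in every alternative that tested them, and of 38 not past, 16 never passed. Precision is limited by 3 arrays per group and, for dim genes, by low signal.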

Other observations

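All tests in this part except the count of splits were chosen after the result was seen. Heart muscle genes varied between lungs of both groups: the mean of 13 genes relative to the control mean was 1.11, -1.32 and 0.21 in control and 1.20, -1.10 and -0.49 in silica (log2). Of 6 adipocyte genes all but Cidea were highest in control replicate 3, with Adipoq at 753 and Plin1 at 266, against 211 and 73.7 in control replicate 1. Cidea had 456 there and 549 in control replicate 1. Poly-A RNA spike probe sets (24) lay lower in silica replicates 1 and 3, with medians of -0.89 and -0.56 (log2, relative to the mean of each over all arrays), against 0.17 to 0.71 on the other 4 arrays. Hybridization spike probe sets (18) had medians of -0.26 and -0.20 in silica replicates 1 and 3, against 0.09 to 0.12 on the other 4 arrays. Spike signal therefore moved partly with the groups, and its cause was not tested. Of the probe sets past the threshold, 44 of the 290 higher and 16 of the 45 lower had no single gene name.

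Interferon-response genes were highest in silica replicate 2, with a mean excess over the other silica arrays of 0.32 ± 0.09 (log2, SE over 20 genes), and 13 of the 20 had their highest silica value there. Other lists stood higher on this array as well, by 0.63 ± 0.09 for neutrophil genes, 0.34 ± 0.06 for antigen presentation and 0.22 ± 0.10 for chemokines, so the pattern is not confined to interferon genes. A greater number of T and NK cells in that lung is argued against by the T and NK cell list, whose excess was -0.072 ± 0.074. A single scaling factor for that array would move both lists alike, but the interferon excess lay 0.395 ± 0.118 (SE over genes) above that of the T and NK list. These SEs take genes as independent and describe 1 array, while the interferon list had an estimated correlation of 0.29. Signal-dependent scaling is argued against by 10000 random lists matched on signal level, whose mean excess was 0.00724 and whose highest was 0.26. No other biological explanation was tested, since the labels name no difference between silica animals, and a change in other leukocytes, such as neutrophils, stays open.

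On average the 12 clock output and repressor genes lay higher in silica, by 0.47 ± 0.09, and the 3 activators lower, at a mean of -0.46 ± 0.22 (log2 fold change, SE over genes). Of these genes 1 output (Bhlhe41) and 1 activator (Bmal1) passed, and the other activators, named after their values were seen, had -0.31 (Clock, adjusted p = 0.189) and -0.18 (Npas2, adjusted p = 0.696). The exact permutation p of the output-minus-activator score was 0.1, the smallest this design allows. RNA degradation as a whole cause is argued against by the fit with the 3-prime to 5-prime ratio as covariate, in which the output-minus-activator score differed by 1.06 ± 0.13 (SE over arrays) against 0.93 ± 0.12 without it. Another time of day at collection may give such a difference (0.927 ± 0.236, SE over genes). Collection times are not given in the sources used here, so that cause cannot be told apart from an effect of silica on the clock. The SEs over genes take genes as independent, while the clock list had an estimated correlation of 0.20.

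The split into control and silica gave 335 probe sets past the threshold in limma. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.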
